A study of Mus musculus with 6 samples.

How the data were processed

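Gene expression and hashtags were measured in NeuN-sorted nuclei of mouse hypothalamus in 3 pools, 1 each for chow, DIO and OB mice. The deposited matrices hold raw UMI counts per gene and hashtag counts per barcode, which the authors made with Cell Ranger and filtered to called cells. Per the labels, reads were aligned with Cell Ranger 6.0.0 to mm10. Per the file headers, the version was 6.0.0 for chow and DIO (27998 genes) but 7.0.1 for OB (31053 genes). Of these, 27514 genes by Ensembl identifier were in all 3 pools. Comparisons of vehicle nuclei between pools and the added test across the pools used these alone. The difference between the rapamycin effects in DIO and chow drew on the 27998 genes that these 2 pools share. The matrices were checked to hold whole numbers only. The OB matrix lists 15 further tags, all with 0 counts. The deposited key gives tag 1 as rapamycin and tag 2 as vehicle.

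Nuclei with at least 500 UMIs, at least 300 genes and under 5% mitochondrial UMIs were kept, which removed 1 of the 12284 OB barcodes and none in chow or DIO. Hashtags were called with HTODemux of Seurat 5.3.0 (R 4.3.3) at a positive quantile of 0.99. Doublets between hashtags numbered 542 in chow, 450 in DIO and 618 in OB and were removed, while doublets within 1 hashtag cannot be seen this way. Nuclei without a call numbered 191, 406 and 3721 and were left out of the comparisons. As an alternative, nuclei were called by a tag ratio. Log2 counts of each tag were centred on their mean over the pool, and 1 tag had to exceed the other at least 2-fold. In OB, this assigned 5312 nuclei to rapamycin and 5338 to vehicle, against 5593 and 2351 with HTODemux. Centring draws the cut towards the middle of the pool, so the near-equal numbers may in part come from the method.

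Nuclei of the 3 pools were clustered together with scanpy 1.11.5 and leidenalg 0.10.2 (Python 3.11.15) on 3000 variable genes, each scaled within its pool, with 40 principal components, 20 neighbours and a resolution of 1.0. This gave 50 clusters, 38 of them neuronal. A cluster was named "X-like" when at least 3 fixed markers of 1 cell type, and more than of any other type, stood over 3-fold above their CPM in all other nuclei (after 5 CPM were added to both) and were seen in over 10% of its nuclei. A cluster without a glial, vascular or pituitary name was neuronal when its neuronal markers had a median fold over 0.5. Named clusters numbered 24, and 25 neuronal clusters stayed unnamed and counted under all neurons. Clusters made without Pomc, Cartpt, Agrp and Npy numbered 49, and clusters made within each pool 41 in chow, 44 in DIO and 28 in OB.

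UMIs were summed per hashtag over all neurons, Pomc-like and Agrp-like neurons, and divided by the total of the sum to give CPM. With 1 hashtag per treatment in a pool, the planned edgeR test within a pool has no replicates. Each comparison is therefore a log2 ratio of CPM with an exact 95% interval for counting error, with no test and no count of changed genes. Where a gene has no UMI in 1 group, a floor of 3 counts is the limit. The floor was 0.088 to 0.102 CPM in chow and DIO neurons and 0.498 in OB vehicle neurons, but 99.3 in OB vehicle Pomc-like neurons. The median of a gene list was set against 10000 random lists of as many genes, matched in 20 bins of expression, and lists needed 5 measured members.

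Comparisons, markers, gene lists, the rule for named genes and the alternatives below, unless said to be added, were fixed before the data were examined. The 18 lists cover leptin signalling, melanocortin and energy balance peptides, mTORC1 and its regulators, ATF4 targets, cholesterol and fatty acid synthesis, ribosomal proteins, glycolysis, oxidative phosphorylation, autophagy and lysosome, endoplasmic reticulum stress, immediate-early genes, insulin and IGF signalling, ionotropic glutamate receptors, GABA-A receptors, heat shock, mitochondrially encoded genes, glial and vascular markers and pituitary markers. The rule names the 10 genes with the highest and the 10 with the lowest ratio among those with at least 50 UMIs in both sums together, and, whatever their value, Pomc, Cartpt, Agrp, Npy, Lepr, Socs3, Mc4r, Pcsk1, Pcsk2, Cpe, Pam, Mtor, Rps6 and Fos. Gene models with numbered names were counted but not named. From these and from the members of lists, the examples in the text were chosen after their values were seen, and their intervals do not allow for that choice.

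An added test, chosen after the data were seen, fitted the 6 sums of the 3 pools together with the pool as a block in edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr, adjusted p of at most 0.05). DESeq2 1.42.0 was its alternative, and camera of limma 3.58.1 tested the lists with a preset correlation of 0.01 and again with an estimated one. It takes the 3 pools as replicates of the rapamycin effect. Tested on simulated data with 2-fold and 4-fold changes, it found 89.0% and 99.0% of them in all neurons, 50.5% and 93.3% in Pomc-like and 60.9% and 92.4% in Agrp-like neurons. Unchanged genes were 13 of the 200 called in all neurons, 2 of 133 in Pomc-like and 12 of 153 in Agrp-like neurons. In simulated Poisson sums for 9 comparisons, the intervals held the true ratio for 95.3% to 96.5% of unchanged genes and 95.0% to 98.5% of changed genes. These sums had no variation between nuclei or mice, so they check the calculation only and not the fit of the intervals to the data.

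Alternatives were TMM and median-of-ratios factors, other UMI filters, hashtag calls by tag ratio, nuclei with at least 1000 UMIs and 500 genes, removal of nuclei above the 99th percentile of UMIs, thinning to equal totals, mean CPM over nuclei, clusters made within each pool and a resolution of 2.0 for shares. Clusters made without the 4 peptide genes, and equal weights of each cluster in both treatments, were added after the data were seen. Equal weights used clusters with at least 20 nuclei per treatment, which hold 98.9% of neurons in chow, 99.2% in DIO and 90.6% in OB. Other tools were numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Gene positions come from the RefSeq annotation of GRCm38.p6.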

Results

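The series measured gene expression in single nuclei of mouse hypothalamus, the brain region that holds the leptin-responsive neurons of the arcuate nucleus. Nuclei positive for NeuN, a neuronal nuclear protein, had been sorted before capture on the 10x Genomics platform. The mice were fed chow, made obese by diet (DIO) or carried the ob/ob mutation, which removes functional leptin (OB). Each of these 3 groups formed 1 pool, in which 1 hashtag marked nuclei of mice given rapamycin, an inhibitor of mTORC1, and 1 hashtag marked nuclei of mice given vehicle. The labels do not say how many mice stand behind a hashtag, so every group is 1 sample with no replicates, and no value compared within or between pools carries a test. Intervals in brackets are 95% intervals for counting error, exact Poisson for counts scaled to the total of a sum (CPM) and exact Clopper-Pearson for shares and for ratios. For medians of gene lists they are order-statistic intervals, which show the spread among genes. None of them covers differences between mice. The intervals for CPM and for ratios take UMIs as independent, so they also leave out variation between nuclei and are too narrow where nuclei differ. Percentiles among random lists take genes as independent, although members of a list can move together, and are no test.

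The chow pool held 10853 barcodes with 68992028 UMIs and a median of 5826 UMIs per nucleus. The DIO pool held 11405 barcodes with 71127440 UMIs and a median of 5572. The OB pool held 12284 barcodes with 39238102 UMIs and a median of 2804.5. Hashtags assigned 4934 nuclei to rapamycin and 5186 to vehicle in chow, 6008 and 4541 in DIO, and 5593 and 2351 in OB. In OB, 3721 nuclei (30.3%) had no hashtag call, against 191 in chow and 406 in DIO. Sums over neurons held 30011453 (rapamycin) and 31691631 (vehicle) UMIs in chow, 34074433 and 29388239 in DIO, and 16373855 and 6018188 in OB.

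Rapamycin was compared with vehicle in Agrp-like neurons, the leptin-inhibited arcuate neurons that drive feeding. Agrp (ENSMUSG00000005705, GRCm38.p6 chromosome 8, 105566695 to 105579845), which encodes an antagonist of melanocortin receptors, was higher with rapamycin in each of the 3 pools. It stood at 477 CPM (417 to 544) against 304 (256 to 359) in chow, 246 (206 to 293) against 175 (141 to 215) in DIO and 649.8 (580.0 to 726) against 242 (168 to 338) in OB. The log2 ratios were 0.65 (0.34 to 0.96), 0.49 (0.09 to 0.90) and 1.42 (0.91 to 1.98). Over all genes with at least 50 UMIs in these neurons, 5% to 95% lay between -0.577 and 0.557 in chow. The range was -0.544 to 0.578 in DIO, which holds the Agrp ratio there, and -0.61 to 0.797 in OB. Npy (ENSMUSG00000029819, chromosome 6, 49822710 to 49829507), an appetite-stimulating peptide of the same neurons, stood at 124 CPM (94.3 to 160.5) against 56.1 (36.6 to 82.2) in chow, 32.4 against 23.6 in DIO and 394 (340.1 to 454) against 149.6 (92.6 to 229) in OB. Its log2 ratios were 1.15 (0.46 to 1.87), 0.46 (-0.69 to 1.66) and 1.40 (0.74 to 2.12). In clusters made without Pomc, Cartpt, Agrp and Npy, the Agrp ratios were 0.62, 0.50 and 1.43 and the Npy ratios 1.10, 0.38 and 1.38. Other neurons in the same samples, where free RNA would appear, held Agrp at 51.6 and 49.4 CPM in chow, 57.4 and 51.1 in DIO and 68.1 and 66.9 in OB (rapamycin, then vehicle), and Npy at 0.85 and 1.46 in chow, 0.45 and 0.42 in DIO and 3.80 and 3.59 in OB. Agrp exceeded Npy by far more there than in Agrp-like neurons, so this Agrp need not all be free RNA of those neurons. Its source was not tested.

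Among the other genes of Agrp-like neurons, Adra1a, an adrenergic receptor, was higher with rapamycin in chow at a log2 ratio of 1.76 (1.06 to 2.51). The synaptic adhesion gene Il1rapl2 was lower there at -1.51 (-1.76 to -1.27). Clusters made within each pool, with 243 Agrp-like nuclei in chow in place of 153, gave -0.75. In DIO, the potassium channel subunit Kcnmb2 was higher at 1.35 (0.62 to 2.13) and Ubqln1, which delivers proteins to the proteasome, was lower at -1.48 (-2.38 to -0.65). In OB, Foxo1, a transcription factor restrained by insulin signalling, was higher at 1.59 (0.48 to 2.96), and Npc1, which exports cholesterol from lysosomes, was higher at 2.33 (0.70 to 4.65) on 52 and 3 UMIs, or 1.28 with hashtags called by the tag ratio. Lepr (ENSMUSG00000057722, chromosome 4, 101717137 to 101815352), the leptin receptor, gave 0.53 (-0.00 to 1.08) in chow, -0.30 (-0.86 to 0.26) in DIO and 0.48 (0.03 to 0.96) in OB, or 0.09 in OB with the tag ratio. Of the 18 lists, the melanocortin and energy balance peptides in OB lay outside the central 95% of random lists, with 5 of 7 measured members higher, a median of 0.39 and percentile 99.4. The sums rest on 78 and 71 nuclei in chow, 97 and 85 in DIO and 142 and 41 in OB, and TMM scaling moves the median over all genes in OB from 0.03 to 0.11.

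**Figure D1:**
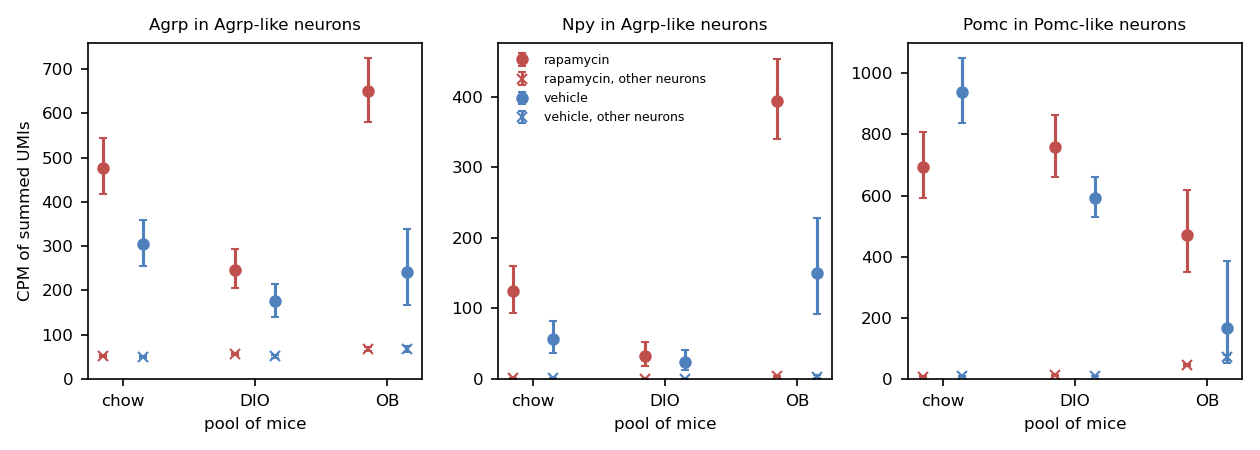
CPM of Agrp and Npy in Agrp-like neurons and of Pomc in Pomc-like neurons by pool, rapamycin in red and vehicle in blue, with circles for the named class, crosses for other neurons and bars for exact Poisson 95% intervals. Agrp lies higher with rapamycin in the 3 pools (477 against 304, 246 against 175 and 649.8 against 242 CPM).

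Pomc-like neurons, the leptin-activated arcuate neurons that restrain feeding, were compared in the same way. Pomc (ENSMUSG00000020660, chromosome 12, 3954945 to 3960643), the precursor of the melanocortin peptide alpha-MSH, stood at 693 CPM (593 to 807) with rapamycin against 939 (838 to 1049) with vehicle in chow, a log2 ratio of -0.44 (-0.72 to -0.16). In DIO it stood at 758 (662 to 863) against 593 (531 to 659.6), a ratio of 0.35 (0.10 to 0.60). In OB it stood at 470.5 (351 to 617) against 165 (53.7 to 386), a ratio of 1.51 (0.19 to 3.19) on 52 and 5 UMIs. When clusters were made without the 4 peptide genes, 276 of the 283 Pomc-like nuclei lay in an unnamed cluster of 556. Pomc ratios in this wider set of nuclei were -0.29 in chow, -0.23 in DIO and 1.54 in OB. Other neurons held Pomc at 8.02 and 8.71 CPM in chow, 12.3 and 9.75 in DIO and 46.4 and 70.6 in OB.

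In chow Pomc-like neurons, Pcsk1, the convertase that begins Pomc cleavage, had 8 UMIs with rapamycin and 32 with vehicle, a log2 ratio of -1.54 (-2.87 to -0.39), which clusters made within each pool brought to -0.05. The chow Pomc-like cluster made within the pool was broader, with 304 nuclei in place of 83. It met the marker rule with Pomc, Tbx3 and Nr5a2 but not with Cartpt or Lepr. Pcsk2, the convertase that acts after Pcsk1, was higher at 0.64 (0.26 to 1.02), and 0.30 in clusters made within each pool. Asb4, a gene of arcuate neurons, was lower at -2.01 (-2.79 to -1.29), or -0.80 in clusters made within each pool and -1.13 in the wider set. In DIO, Cartpt, an appetite-restraining peptide, was higher at 0.58 (0.12 to 1.03), or 0.20 in the wider set. The growth factor receptor Igf1r was lower in DIO at -1.33 (-2.32 to -0.45), as were the phosphodiesterase Pde3a at -1.70 (-3.09 to -0.53) and the glycine receptor subunit Glra3 at -1.40 (-2.43 to -0.49). In OB, the glutamate receptor Grm8 was higher at 1.34 (0.29 to 2.60). Lepr gave -0.03 (-0.64 to 0.57) in chow and -0.10 (-0.71 to 0.49) in DIO, so that no difference was detectable at this depth. Intervals that exclude 0 can arise here too from the choice of genes by their ratios. Over all genes with at least 50 UMIs, 5% to 95% lay between -0.603 and 0.602 in chow, -0.597 and 0.575 in DIO and -0.83 and 0.965 in OB. The sums rest on 35 and 47 nuclei in chow, 47 and 87 in DIO and 36 and 8 in OB, where TMM scaling moves the median over all genes from -0.03 to 0.23.

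Across all neurons of the chow pool, genes of cholesterol and fatty acid synthesis, the targets of the SREBP transcription factors, were lower with rapamycin in 22 of 24 measured members. Their median log2 ratio was -0.21 (-0.25 to -0.12), below every one of the 10000 random lists matched in expression. Members included Hmgcs1, an early enzyme of cholesterol synthesis, at -0.33 (-0.45 to -0.21) and Fdft1, which makes squalene, at -0.24 (-0.36 to -0.12). Autophagy and lysosome genes were lower in 27 of 32 members, with a median of -0.09 (percentile 0.09), among them Lamp2 at -0.26 (-0.36 to -0.16). Heat shock genes were lower in 12 of 12 members, with a median of -0.12 (percentile 0.12), among them Hsp90aa1 at -0.17 (-0.27 to -0.06). Ionotropic glutamate receptors were higher in 12 of 16 members, with a median of 0.06 (percentile 99.5), among them Grid1 at 0.15 (0.12 to 0.18), and equal weights for the clusters brought the median to 0.04. Genes of mTORC1 and its regulators, the pathway that rapamycin inhibits, had a median of -0.03 with 23 of 34 lower (percentile 47.8).

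Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477274), an immediate-early gene induced by neuronal activity, was higher with rapamycin in chow neurons at a log2 ratio of 0.59 (0.28 to 0.89) on 219 and 154 UMIs. The developmental transcription factor Pax6 was higher at 1.31 (0.89 to 1.73). Npvf, which encodes an RFamide peptide, was lower at -1.40 (-2.15 to -0.69) on 23 and 64 UMIs. Cartpt was lower at -0.46 (-0.63 to -0.29), or -0.24 with each cluster at the same weight in both treatments, and the melanocortin receptor Mc4r was lower at -0.61 (-1.23 to -0.01) on 39 and 63 UMIs. Lepr gave 0.08 (-0.06 to 0.23), Socs3, an inhibitor of leptin signalling, 0.40 (-0.42 to 1.24), and Mtor -0.06 (-0.16 to 0.03). RNA of blood cells was unequal, as haemoglobin Hbb-bs was lower at -1.17 (-1.92 to -0.46), while glial and vascular markers had a median of 0.04 (-0.18 to 0.15). Over 15503 genes with at least 50 UMIs, the median ratio was -0.03 and 5% to 95% of genes lay between -0.32 and 0.23.

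Across all neurons of the DIO pool, immediate-early genes, the rapid transcriptional response to neuronal activity, were lower with rapamycin in 12 of 14 measured members. Their median was -0.76 (-1.44 to -0.12), below every one of the 10000 random lists. Fos was at -1.96 (-2.46 to -1.49) on 48 and 161 UMIs, Egr1 at -1.71 (-2.24 to -1.19) and Npas4, which responds to calcium entry in neurons, at -0.93 (-1.25 to -0.62), while Jun at 0.17 (-0.15 to 0.48) and Ier5 at 0.30 (-0.35 to 0.97) were the 2 members that were not lower. Ribosomal protein genes were higher in 51 of 56 members, with a median of 0.19 (0.14 to 0.24) above every random list, among them Rpl9 at 0.34 (0.21 to 0.47). Nuclear genes of oxidative phosphorylation were higher in 35 of 36 members, with a median of 0.16 (percentile 99.96), among them Cox8a at 0.29 (0.17 to 0.42).

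Mitochondrially encoded genes in DIO neurons were lower in 9 of 10 members with a median of -0.31 (-0.48 to -0.14). Among them mt-Nd2 was at -0.90 (-1.22 to -0.57) on 129 and 207 UMIs. The median nucleus held 0.0% mitochondrial UMIs in each pool, so these values rest on few UMIs in sorted nuclei. RNA carried over from outside the nuclei was not told apart from a change in the neurons. Cholesterol and fatty acid synthesis genes were lower in 20 of 25 members, with a median of -0.10 (-0.15 to -0.01) below every random list, although Scd2, a fatty acid desaturase, was higher at 0.37 (0.23 to 0.51). Leptin signalling genes were lower in 11 of 15 members, with a median of -0.11 (percentile 0.13). Lepr among them was at -0.27 (-0.40 to -0.15), or -0.13 with equal cluster weights, and Irs2, an adaptor of insulin and leptin signalling, at -0.37 (-0.57 to -0.17). Melanocortin and energy balance peptides were lower in 15 of 21 members, with a median of -0.10 (percentile 0.07) that equal cluster weights brought to -0.05. Insulin and IGF signalling genes were lower in 16 of 21 members, with a median of -0.06 (percentile 1.45), and heat shock genes were higher in 10 of 12, with a median of 0.16 (percentile 99.2). The mTORC1 list had a median of 0.01 with 20 of 34 higher (percentile 31.6).

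Among the lowest ratios in DIO neurons were those of Abhd12b at -2.82 (-3.79 to -1.96) and the kinase Prkcd at -2.10 (-2.99 to -1.28), but equal cluster weights gave 0.15 and -0.37. Equal weights left out the rare thalamic-type neurons, which numbered 1 nucleus with rapamycin and 20 with vehicle. Abhd12b leads their markers and Prkcd is among them, so both equal-weight values are ratios over the remaining clusters. Cd38, an enzyme that consumes NAD, was lower at -1.87 (-2.89 to -0.94), or -1.08 with equal weights. RNA of other cell types was also unequal, since Gh, the growth hormone gene of the pituitary, was higher at 2.08 (1.02 to 3.30) on 44 and 9 UMIs, and the endothelial gene Emcn was higher at 1.25 (0.51 to 2.05).

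Across all neurons of the OB pool, heat shock genes were higher with rapamycin in 12 of 12 measured members, with a median of 0.28 (0.15 to 0.46) above every random list. Dnaja1 was at 0.49 (0.32 to 0.68) and Hspa8 at 0.39 (0.19 to 0.58). Genes of the endoplasmic reticulum stress response were higher in 16 of 21 members, with a median of 0.17 (0.04 to 0.40, percentile 99.8), or 0.11 in clusters made within each pool. Among them the chaperones Hspa5 and Hsp90b1 were at 0.63 (0.35 to 0.92) and 0.43 (0.25 to 0.62). Glycolysis genes were higher in 19 of 23 members, with a median of 0.13 (percentile 98.5), which sums thinned to the same total brought to 0.07, and insulin and IGF signalling genes in 16 of 21, with a median of 0.12 (percentile 98.3). Ribosomal protein genes were higher in 42 of 56 members, with a median of 0.10 (percentile 97.6) or 0.24 with hashtags called by the tag ratio. Mitochondrially encoded genes were lower in 6 of 9 members, with a median of -0.24 (-0.37 to 0.24) and percentile 0.20, or -0.02 with the tag ratio. They carry the limit given for DIO, as the median OB nucleus also held 0.0% mitochondrial UMIs. The mTORC1 list had a median of 0.09 with 24 of 33 higher (percentile 93.5).

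Single genes in OB neurons rest on fewer UMIs. Gal, which encodes the peptide galanin, was higher with rapamycin at 2.46 (1.59 to 3.49) on 165 and 11 UMIs, or 1.64 with the tag ratio. Prok2, a signal of the suprachiasmatic nucleus, was higher at 4.20 (1.66 to 9.53) on 50 and 1 UMIs, or 2.39 with the tag ratio and 1.92 with equal cluster weights. Npy was higher at 1.07 (0.61 to 1.57), and Mc4r was higher at 2.26 (0.60 to 4.60) on 39 and 3 UMIs, or 1.18 with the tag ratio. Rps6, a ribosomal protein phosphorylated downstream of mTORC1, was higher at 0.41 (0.03 to 0.81), and Pcsk1 was lower at -0.67 (-0.87 to -0.47), or -0.29 with the tag ratio and -0.39 with equal cluster weights. Gh was lower at -1.98 (-2.45 to -1.51), or -1.19 in clusters made within each pool, and glial and vascular markers had a median of -0.14 (-0.34 to 0.31, percentile 3.03).

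Some lists lay within the central 95% of random lists in every pool. For genes of GABA synthesis and GABA-A receptors, the medians were 0.00 in chow, 0.02 in DIO and 0.03 in OB. For ATF4 targets and amino acid synthesis, which respond to mTORC1 in other cells, they were -0.01, 0.09 and -0.09. The pituitary markers had fewer than 5 measured members in every pool and no median.

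**Figure D2:**
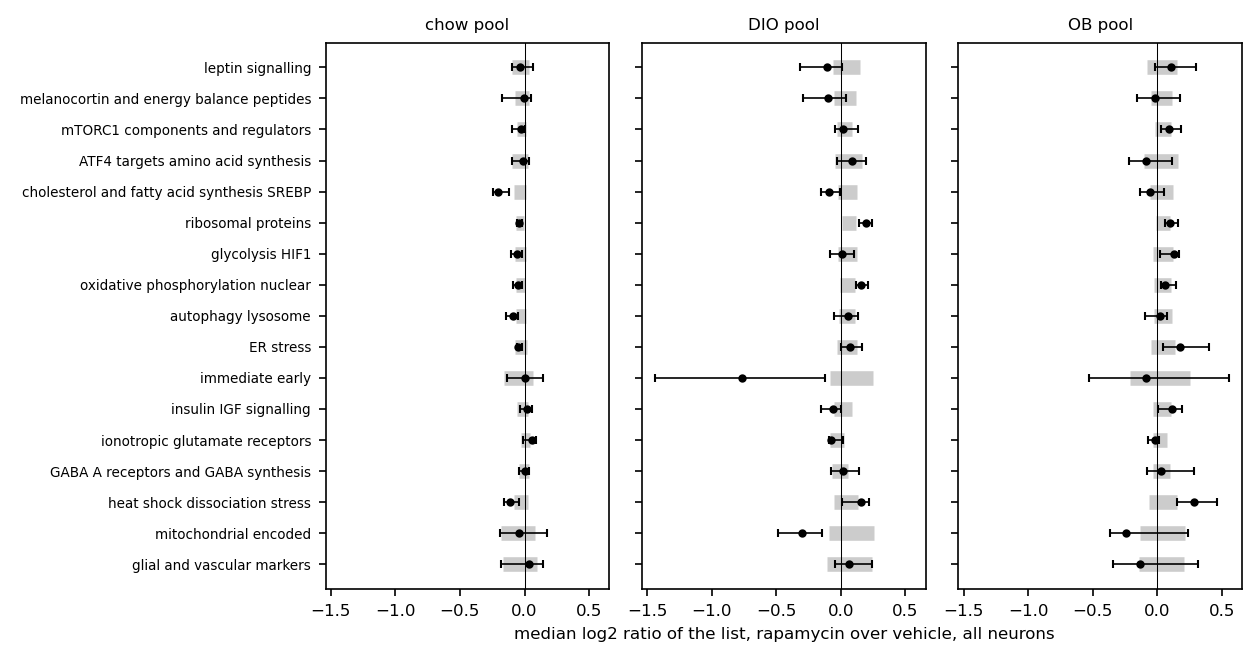
Median log2 ratio of rapamycin over vehicle for each gene list in all neurons, by pool, with bars for the order-statistic 95% interval of the median and grey bands for the central 95% of 10000 expression-matched random lists. The cholesterol and fatty acid synthesis list lies at -0.21 in chow, -0.10 in DIO and -0.06 in OB (0.01 in OB with the tag ratio), and the immediate-early list at -0.76 in DIO.

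The difference between the rapamycin effects in DIO and in chow was taken as the log2 ratio in DIO minus that in chow. It was -2.55 for Fos, -2.45 for Slc6a3, the dopamine transporter, and -2.26 for Pax6. In Slc6a3 the chow ratio of 1.20 became -0.09 with equal cluster weights, which left out the dopaminergic-like neurons (8 chow nuclei). The immediate-early list had a median difference of -0.67 with 12 of 14 members lower, below every random list. Ribosomal protein genes had a median difference of 0.23 (49 of 56 higher), oxidative phosphorylation genes 0.21 (34 of 36 higher) and heat shock genes 0.20 (11 of 12 higher, percentile 98.8). Insulin and IGF signalling genes had a median difference of -0.11 (16 of 21 lower, percentile 0.06), and leptin signalling genes -0.09 (11 of 15 lower, percentile 1.0). The median over all 15298 genes was 0.07, and with 1 sample per group the difference was not tested.

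Vehicle-treated DIO and chow neurons were compared next. Lepr was higher in DIO at a log2 ratio of 0.59 (0.46 to 0.73), and Socs3, which is induced by leptin and limits its signalling, at 1.17 (0.44 to 1.93) on 50 and 24 UMIs. Leptin signalling genes as a list were higher in 10 of 15 members, with a median of 0.17 (-0.13 to 0.49, percentile 97.7). Npy was lower in DIO at -1.46 (-2.19 to -0.77), and in Agrp-like neurons Agrp was lower at -0.80 (-1.20 to -0.40) and Npy at -1.25 (-2.37 to -0.21). Ribosomal protein genes were lower in 55 of 56 members, with a median of -0.52, and oxidative phosphorylation genes in 33 of 36, with a median of -0.37, both below every random list. Cga, a pituitary hormone subunit, was higher at 3.34 (2.29 to 4.60), and haemoglobin Hbb-bs was lower at -3.14 (-4.64 to -1.93). Diet and pool coincide, so differences in capture and in free RNA cannot be told apart from diet. Equal cluster weights were not applied between pools, so a different mix of neuronal clusters stays open for the all-neuron values, Lepr among them. An unnamed neuronal cluster with Lepr among its leading markers held 128 nuclei in chow and 208 in DIO, treatments together.

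Vehicle-treated OB and chow neurons were set side by side with the same limit. Npy was higher in OB at 1.72 (1.15 to 2.29), Agrp at 0.45 (0.29 to 0.60) and Lepr at 0.37 (0.13 to 0.60). In Agrp-like neurons Lepr was higher at 1.68 (1.08 to 2.28) and Npy at 1.43 (0.53 to 2.32), while Agrp gave -0.31 (-0.90 to 0.24), and Agrp in other neurons stood at 66.9 CPM in OB and 49.4 in chow. Cholesterol and fatty acid synthesis genes were lower in 19 of 24 members, with a median of -0.35 (-0.50 to -0.02) below every random list, and ionotropic glutamate receptors were higher in 13 of 16, with a median of 0.21 (percentile 99.7). Mitochondrially encoded genes were higher in 9 of 9 members, with a median of 1.40, glial and vascular markers in 9 of 9, with a median of 0.48, or 0.99 with a filter of 10 UMIs, and Gh was higher at 7.43 (5.84 to 9.73) on 97 and 3 UMIs. The OB files came from another Cell Ranger version and gene annotation, and genes such as Zfp935, with 2 UMIs in OB and 1199 in chow, stand at the extremes.

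Shares of named classes among nuclei with a hashtag call were compared between the treatments. Paraventricular-like neurons, which include neuroendocrine cells, were 1.03% (0.771 to 1.36) of nuclei with rapamycin and 1.60% (1.28 to 1.98) with vehicle in chow, 1.62% (1.31 to 1.97) and 3.41% (2.90 to 3.98) in DIO, and 1.31% (1.02 to 1.64) and 2.64% (2.03 to 3.37) in OB. Histaminergic-like neurons were 0.816% (0.604 to 1.08) and 1.48% (1.15 to 1.87) in DIO and 0.483% (0.318 to 0.702) and 1.23% (0.828 to 1.77) in OB, but 0.770% and 0.636% in chow. Suprachiasmatic-like neurons were 1.27% (0.998 to 1.58) and 0.462% (0.286 to 0.706) in DIO and 2.25% (1.88 to 2.68) and 0.425% (0.204 to 0.781) in OB, against 0.466% and 0.675% in chow. Agrp-like neurons were 1.58% and 1.37% in chow, 1.62% and 1.87% in DIO and 2.54% and 1.74% in OB (with vehicle 1.35% in chow and 1.79% in OB in clusters made without the peptide genes, and 2.31% and 2.41% in chow in clusters made within each pool). Pmch-like neurons of the lateral hypothalamus, which make melanin-concentrating hormone, were 0.516% (0.351 to 0.732) and 1.23% (0.933 to 1.60) in DIO. In chow they were 22 of 4934 nuclei with rapamycin and 32 of 5186 with vehicle. In OB they numbered 22 nuclei, with or without a call. Pomc-like neurons were 0.709% and 0.906% in chow, 0.782% and 1.92% in DIO and 0.644% and 0.340% in OB. They were 2.74% and 3.20% in chow in clusters made within each pool, where the Pomc-like cluster was broader (304 chow nuclei in place of 83). The unnamed cluster of 556 nuclei, made without the peptide genes, held 1.42% and 1.79%, 1.88% and 2.78%, and 1.59% and 0.766%.

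The NeuN sort, dissection and hashtag calls set which nuclei can be counted. All neurons were 94.6% and 95.6% of called nuclei in chow, 95.2% and 94.9% in DIO, but 81.8% and 62.7% in OB, where 30.3% of nuclei had no call and the median depth was lowest. The OB shares above are of called nuclei, so they also carry this difference in neurons. Among OB neurons, Agrp-like were 142 of 4577 with rapamycin and 41 of 1475 with vehicle, and paraventricular-like were 73 and 62.

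**Figure D3:**
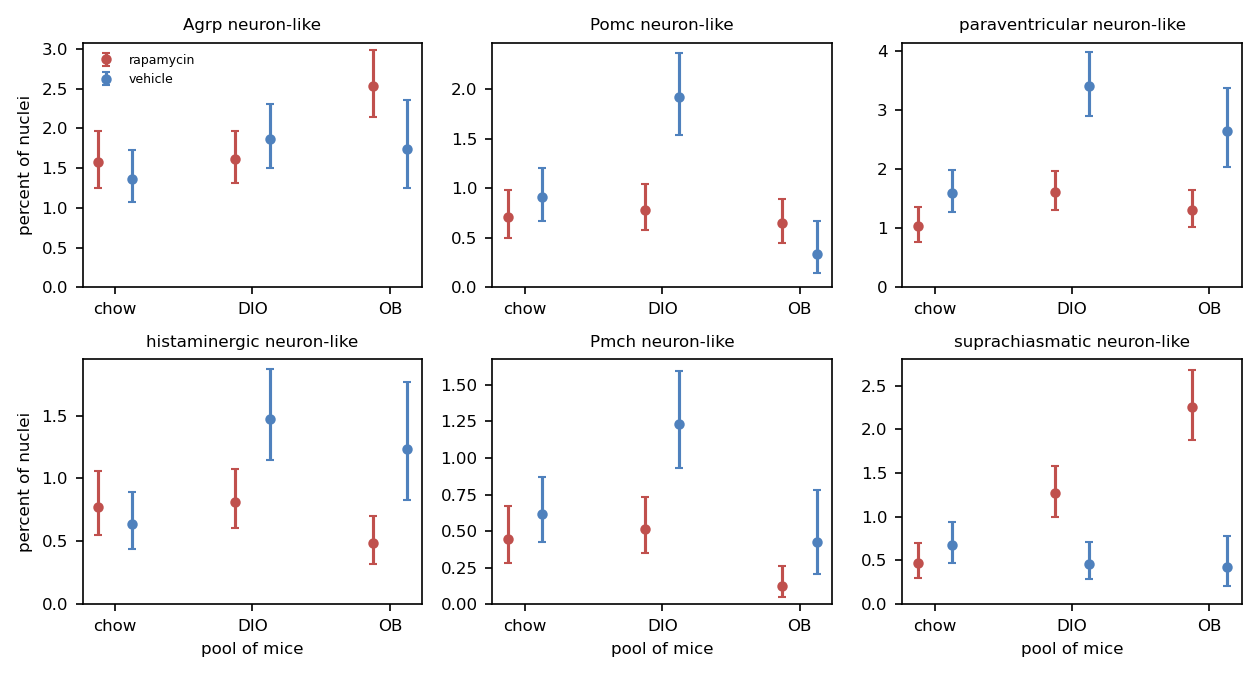
Percent of nuclei with a hashtag call that fell in 6 named neuronal classes, by pool, rapamycin in red and vehicle in blue, with exact binomial 95% intervals. Paraventricular-like neurons lie lower with rapamycin in the 3 pools (1.03% against 1.60%, 1.62% against 3.41% and 1.31% against 2.64%). In OB, neurons were a smaller part of the called nuclei with vehicle than with rapamycin, which also shifts these shares.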

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

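Of the tests in this part, only the count of neuronal clusters with lower immediate-early UMIs had its outcome written down before the result was seen, and all others were chosen after. None of the differences between pools given here was tested, since each pool holds 1 sample per treatment.

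Agrp was higher with rapamycin in Agrp-like neurons of the 3 pools, and Npy in chow and OB, with 0.46 (-0.69 to 1.66) in DIO; the tests here concern Agrp. Free RNA would raise Agrp in other neurons by as much, but their difference in CPM was at most 8.83% of that in Agrp-like neurons. Selection of nuclei by the peptides themselves would remove the ratio in clusters made without them, where the lowest Agrp ratio of the pools was 0.50. What stays open is chance differences between the mice behind the hashtags, since 3 pools allow no p under 0.25 in an exact two-sided sign test. An effect of rapamycin stays open as well, since the added test across the pools gave Agrp an adjusted p of 0.0452 by edgeR, while DESeq2 called 0 genes.

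Immediate-early genes were lower with rapamycin in DIO neurons, and Fos was higher in chow, so that the log2 ratios of Fos differed by -2.55 between these pools. Another mix of neuronal clusters was argued against, as the list median with each cluster at the same weight was -0.63 (-1.19 to -0.13). A few clusters with high values were argued against, since 88.6% of 35 DIO clusters (31) had lower summed CPM of the list, against 18 of 35 in chow and 9 of 27 in OB. Weaker dissociation stress in the rapamycin nuclei stays open, since heat shock genes had a median of 0.16 (0.005 to 0.22) whose interval reaches -0.031 with other scaling factors. Handling of the mice before death stays open and cannot be told apart from rapamycin, because 1 hashtag per treatment stands behind the values.

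Genes of cholesterol and fatty acid synthesis were lower with rapamycin in chow and DIO neurons. In chow, another mix of neuronal clusters was argued against, as equal cluster weights left a median of -0.23 (-0.29 to -0.11). In DIO, equal weights gave -0.073 (-0.133 to 0.021), which decides nothing. RNA from glial cells, which make much cholesterol, stays open in both, with medians of glial and vascular markers of 0.038 (-0.184 to 0.146) in chow and 0.064 (-0.048 to 0.241) in DIO. Chance differences between mice stay open with the same limit of 0.25 in the exact sign test, and an effect of rapamycin stays open, with an adjusted p of 1.57e-07 for the list by camera across the pools but 0.649 with an estimated correlation.

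Other values stood out because the intervals of 2 pools lay on opposite sides of 0. In all neurons, Mc4r ratios differed by 2.87 between OB (2.26 on 39 and 3 UMIs, or 1.18 with the tag ratio) and chow (-0.61). Between OB and DIO, Pcsk2 differed by 0.19 and Cpe, an enzyme of peptide maturation, by 0.26. For lists, the value here is the difference between the medians of 2 pools, not the median of the differences of single genes given earlier. Ribosomal protein genes differed from chow (-0.04) by 0.23 in DIO and 0.14 in OB. Oxidative phosphorylation genes differed from chow by 0.20 in DIO and 0.11 in OB, and heat shock genes by 0.27 in DIO and 0.40 in OB. Glycolysis genes differed by 0.19 and endoplasmic reticulum stress genes by 0.22 between OB and chow, and insulin and IGF signalling genes by 0.17 between OB and DIO. With TMM scaling the chow median over all genes moves from -0.028 to -0.005, and the chow intervals of the ribosomal, oxidative phosphorylation, glycolysis and endoplasmic reticulum stress lists and of Mc4r then reach past 0, as do the OB intervals of glycolysis and of insulin and IGF signalling and the DIO interval of heat shock genes. Pomc in Pomc-like neurons differed from chow by 0.79 in DIO and 1.94 in OB, while the DIO ratio was -0.23 in the wider, unnamed cluster of 556 nuclei made without the peptide genes.

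A pair of signals came from nuclei outside the comparisons. Pituitary-like nuclei were 2.15% (1.90 to 2.43) of the 11665 OB nuclei left without hashtag doublets, against 0.068% in chow and 0.539% in DIO. The 53 Agrp-like nuclei of OB without a hashtag call held Agrp at 232 CPM (164 to 318) on 38 UMIs, beside 242 with vehicle and 649.8 with rapamycin.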

How the results depend on the processing

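Main values were the median of the mTORC1 list in all neurons, or of the leptin signalling list for vehicle nuclei between pools. The others were Pomc or Agrp in its class, the shares of the 2 classes and counts of genes called across the pools. Of 220 comparisons of a main value with an alternative, 195 stayed within its interval and 25 moved, with 5 of opposite sign. The interval was for counting error in genes and shares, the order-statistic one for list medians, and 1.5 times either way for counts of genes. All other lists are counted separately as medians of lists. For medians of lists 1665 of 1679 stayed, with 124 of opposite sign, and for named genes 3456 of 3560, with 59 of opposite sign. Without the peptide genes, most Pomc-like nuclei (276 of 283) lay in an unnamed cluster of 556, where Pomc in DIO was -0.23 in place of 0.35 and the shares were 1.42% (rapamycin) and 1.79% (vehicle) in chow, 1.88% and 2.78% in DIO and 1.59% and 0.766% in OB. Clusters made within each pool, where the chow Pomc-like and Agrp-like clusters were broader, gave Pomc-like shares of 2.74% and 3.20% and Agrp-like shares of 2.31% and 2.41% in chow. A resolution of 2.0 gave 1.997% Agrp-like nuclei with rapamycin in DIO. Genes called by edgeR across the pools (68 in all, 3 in Pomc-like and 7 in Agrp-like neurons) became 0, 0 and 0 with DESeq2 (168, 12 and 28 at an unadjusted p under 0.05), 209, 0 and 0 without the chow pool, and 0, 0 and 0 without the DIO pool (597, 134 and 324 unadjusted). Without the OB pool 16 were called in all neurons, with the tag ratio 35 in all and 1 in Pomc-like neurons, and 1 in the unnamed cluster. The cause was not tested. Leaving out a hashtag leaves no comparison, the key pairs no animals for a replicate block, and OB has no Pomc-like class in clusters made within the pool. DESeq2, the edgeR filters and the estimated correlation gave no value within a pool and were run across the pools only. Depth limits the OB Pomc-like values most, with 403 genes at 50 UMIs or more.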

Other observations

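The test across the 3 pools, its splits and its list tests were all chosen after the data were seen, and take the pools as replicates. Genes named here and below were called from these same pools, so an equal direction in the pools is no further support. In all neurons, Pcsk1n, an inhibitor of the convertase Pcsk1, rose with rapamycin by 0.53 on the log2 scale by edgeR (adjusted p = 1.96e-13), the granins Scg2 and Chgb by 0.32 (adjusted p = 6.57e-05) and 0.30 (adjusted p = 0.0204), and the opioid precursor Penk by 0.58 (adjusted p = 0.00497), each higher in 3 of 3 pools. Hmgcs1 changed by -0.31 (adjusted p = 0.00755) and was lower in 3 of 3 pools. Pomc changed by -0.38 (adjusted p = 5.11e-04), Cartpt by -0.37 (adjusted p = 0.00997) and Sim1, a transcription factor of paraventricular neurons, by -0.32 (adjusted p = 1.56e-04), each lower in 3 of 3 pools. The interval within chow held 0 for Chgb (-0.076 to 0.206) and Penk (-0.053 to 0.508). So did that of Pomc in DIO (-0.309 to 0.015) and of Cartpt in OB (-0.763 to 0.086). With the tag ratio Pomc was at -0.24 (adjusted p = 0.222) and Cartpt at -0.29 (adjusted p = 0.199), neither called, and Sim1 at -0.29 (adjusted p = 0.0029). Pomc also leads the markers of the pituitary-like cluster. At equal cluster weights in chow, DIO and OB, Pomc was at -0.256, 0.35 and -0.264, and Cartpt at -0.238, -0.04 and -0.253. Sim1 was at -0.045, -0.155 and 0.11. The equal weights in OB left out the Pomc-like cluster, which had 8 nuclei with vehicle. Hdc, which makes histamine, changed by -0.58 (adjusted p = 5.9e-10), with 0.26 in chow, -0.97 in DIO and -1.23 in OB, but equal weights gave 0.13, -0.21 and 0.14.

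In all, edgeR called 68 of 17702 genes in all neurons, 17 higher and 51 lower (980 at an unadjusted p under 0.05), where DESeq2 called 0 (168 unadjusted). Without the DIO pool edgeR called 0 (597 unadjusted), without the OB pool 16 and without the chow pool 209. With the tag ratio it called 35, 14 higher and 21 lower. Of the 68 genes, 51 had the same direction in the 3 pools, 42 of them also at equal cluster weights, and 23 had at most 0.5 of their mean size there. The choice of these genes from the same pools favours an equal direction. In camera, 9 of the 18 lists were called. Cholesterol and fatty acid synthesis genes were lower as a set (adjusted p = 1.57e-07, and adjusted p = 0.649 with an estimated correlation), as were melanocortin and energy balance peptides (adjusted p = 2.81e-04), pituitary markers (adjusted p = 7.37e-04), both at an adjusted p of 0.577 with an estimated correlation, and immediate-early genes (adjusted p = 5.35e-06, and adjusted p = 0.769 with an estimated correlation). The immediate-early medians within the pools were 0.01 in chow, -0.76 in DIO and -0.09 in OB. Ribosomal protein genes were higher (adjusted p = 1.39e-06, and adjusted p = 0.783 with an estimated correlation), although their median was -0.04 in chow beside 0.19 in DIO and 0.10 in OB, and none of the 9 lists is called with an estimated correlation.

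In Agrp-like neurons 7 of 8261 genes were called by edgeR (417 unadjusted), each at an adjusted p of 0.0452, and 0 by DESeq2 (28 unadjusted). Npy rose by 1.13, Agrp by 0.79 and Pcsk1n by 0.94, each higher in 3 of 3 pools, and the potassium channel subunit Kcnmb2 rose by 1.09. Nkain2 changed by -0.82 and was lower in 3 of 3 pools, and 2 gene models changed by -1.04 and -0.78. In Pomc-like neurons 3 of 5913 were called by edgeR (213 unadjusted) and 0 by DESeq2 (12 unadjusted). These were a gene model at -1.03 (adjusted p = 3.11e-05), Cd38 at -2.42 (adjusted p = 0.0285) and the calcium channel subunit Cacna2d3 at -0.77 (adjusted p = 0.0423). Without the chow pool or without the DIO pool, edgeR called 0 in both classes (321 and 324 unadjusted in Agrp-like, 180 and 134 in Pomc-like neurons).

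The 10 splits of the 6 sums are too few for a share under 0.05. In all neurons 1 of the 10 splits, the real one, gave as many as 68 genes, and the highest other gave 44. In Pomc-like neurons 5 of the 10 gave as many as 3, with 3 the highest other, and in Agrp-like neurons 3 of the 10 gave as many as 7, with 11 the highest other. Pools pair the sums, and 6 of the 10 splits part only 1 pool. Among the 4 that part the 3 pools, the highest other gave 44, 2 and 1 genes in all, Pomc-like and Agrp-like neurons.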
